A study of Drosophila melanogaster with 6 samples.

How the data were processed

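Gene expression was measured in whole embryos of 2 genotypes, Oregon R wild type and foxL1 null, with 3 Affymetrix Drosophila Genome 2.0 arrays each. Per the labels' protocols, embryos were dechorionated, total RNA was extracted with Trizol and cleaned on a column, and biotinylated RNA was made with a 3' amplification kit. The labels give 100 ng of RNA per sample in the design text and about 200 ng in the extraction protocol. They give stages 11 to 15 for every sample, and a collection of 8 h followed by 11 h of ageing. The deposited values are log2 expression values from robust multi-array averaging (RMA), per the submitters' processing notes, which name Partek and RMA without versions; the scale was checked on the values, whose median per array lay between 4.87 and 5.08. RMA corrects the background, sets all arrays to a shared distribution and summarises the probes of a probe set, so a change shared by most transcripts is removed and changes of weakly expressed genes are compressed. The 25th percentile lay at 2.97 to 3.01, depending on the array, near the floor. No detection calls were used here, so a fold from such a level is compressed by the background. No 2 arrays shared the identical value at more than 0.0852% of probe sets, so each was counted as its own sample. The 3' minus 5' difference of the actin, GAPDH and eIF-4a control probe sets, a sign of RNA quality, was 0.69 ± 0.02, 0.46 ± 0.03 and 0.88 ± 0.01 in the wild type and 0.57 ± 0.33, 0.55 ± 0.07 and 0.85 ± 0.13 in the null group (log2, mean ± SD, n = 3 each). Null array 3 stood apart, with 0.20 for actin and 0.71 for eIF-4a, the lowest of the 6 arrays, as was its array weight, 0.317; leaving it out gave 1513 called probe sets and 3 called lists.

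The table held 18952 probe sets. The 183 control probe sets were left out of the tests of genes, which left 18769. Of these 13647 named 1 gene, 402 named several and 4720 are unnamed here because no gene was listed for them. Of the 13647, 13544 took their current symbol through the gene identifier from a RefSeq gene table (assembly Release 6 plus ISO1 MT) and 103 kept the older symbol. That table was used only for names and for the order of genes, since the sources used here name no genome build. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays, which gave 11983 genes, and other probe sets were set beside it where they disagreed. No gene was named from a probe set with several genes, and list members without a probe set of their own were not analysed here.

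Groups came from the genotype labels. Differences are null minus wild type on the log2 scale, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 without covariates. P-values are 2-sided and adjusted by Benjamini and Hochberg over all 18769 probe sets, with a threshold of 0.05; the standard errors printed are limma's. Before the data were examined, 32 gene lists were fixed for the tissues and processes of a whole embryo, together with the rule for naming genes, the tests and all alternatives. The rule takes FoxL1, the 10 largest rises and 10 largest falls with no overlap between the genotypes (symbols of the CG form counted, but printed only among the first 4 each way), up to 4 members per list by smallest p, and any of the 20 neighbours of FoxL1 past the threshold. Where no member of a list passed, members are named only for the semaphorin, salivary gland, muscle and attachment lists. Lists were tested with camera at its preset correlation of 0.01, with the adjustment over the 32 lists, and again with an estimated correlation and with fry. A call adjusted over the list alone uses the same limma p with the adjustment restricted to the list. The neighbours were compared with all other genes by Fisher's exact test. The threshold rests on 3 arrays per group, and genotype cannot be told apart from line, since each genotype came from a line of its own.

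The titles number the samples d1 to d3 in both genotypes without saying what the number marks. The correlation of same-numbered arrays' deviations from their group means was 0.108, 0.544 and 0.224, all above 0.1, so the numbers were taken to pair the arrays on the basis of these correlations, which come from the data and not from the labels. Array 1 of the wild type correlated more with null array 3 (0.266) than with its own number. That exchange, with wild-type array 3 set beside null array 1 (0.060), would match the arrays about as well. Deviations from a group mean sum to 0, so these correlations are not independent, and only pair 2 stood out. The data thus do not settle the pairing, and blocked values are given as an alternative. The planned fit has no block, and the blocked value is given where it changes the call of a list or of a gene named by the rule and printed here, or moves a count by over 1.5 times.

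The alternatives were the replicate block, each array left out in turn, another quantile normalization, centring each array on its median, eBayes with trend and robust (statmod 1.5.0), array weights, filters at the 25th and 50th percentile of the mean signal, an unmoderated model, minimum folds of 1.5 and 2, 1 probe set per gene, leaving out probe sets with the suffixes for shared transcripts, averaging a gene's probe sets, and leaving out genes shared by lists. Data were simulated at 18769 probe sets with the real means, 200 of them changed. The noise was normal and alike in both groups, with the spread that limma estimates by sharing across probe sets. The limma step recovered 25.4% of changes of 1.5-fold, 91.0% of 2-fold and 98.5% of 4-fold. Of its calls 5.92% were unchanged probe sets. The real data had 1472 calls and a spread that can differ between groups, so these rates do not carry over to them. Camera called 5 of 5 shifted lists and 0 others, but the noise was drawn independently for each probe set. The simulated lists thus held no correlation between genes, while the called real lists had estimated correlations of 0.051 to 0.588. This camera result therefore does not bear on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.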

Results

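Total RNA from whole Drosophila melanogaster embryos was hybridised to the Affymetrix Drosophila Genome 2.0 array, a set of oligonucleotide probes that reports transcript levels across the fly genome. Embryos lacking FoxL1, a forkhead transcription factor studied for its part in the placement of the salivary gland and other embryonic organs, came from parents that carried a deletion allele over a second foxL1 allele. Embryos of the wild-type line Oregon R, which the labels describe as matched for stage, were the control. Each genotype had 3 arrays, which the labels describe as independent biological samples, from embryos of stages 11 to 15. The protocol gives a collection of 8 h and a further 11 h of ageing at room temperature, which seems later than these stages, and the sources used here do not settle which of them holds. The arrays correlated at 0.990 to 0.995 within the wild type, 0.987 to 0.993 within the null group and 0.980 to 0.989 between the groups (Pearson's r across probe sets of log2 values, which are not independent replicates). The first principal component, with 48.1% of the variance, separated the genotypes. The number of arrays limits the precision of every value.

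The FoxL1 transcript fell in the null embryos, to a level 2.02-fold below the wild type. Its only probe set had a log2 signal of 5.00 ± 0.14 in the wild type and 3.98 ± 0.54 in the null group (mean ± SD, n = 3 each; limma log2 difference -1.01, SE 0.25, adjusted p = 0.0489). The wild-type arrays read 4.85, 5.13 and 5.01 and the null arrays 4.23, 4.35 and 3.37, with no overlap. The wild-type level lay at percentile 49.8 of all probe sets and the null level at percentile 42.2. Which part of the gene the alleles remove is not given in the sources used here, so whether the probe set lies inside it is open. The call ended when wild-type array 1, 2 or 3 or null array 1 was left out (limma adjusted p = 0.109, 0.133, 0.155 and 0.0799). It also ended under both other scalings of the arrays (0.0761 and 0.0641) and held with the replicate numbers as a block (0.0120).

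No measured gene near FoxL1 on chromosome arm 3L passed the threshold in the main limma fit. Of the 10 nearest genes on either side, in the gene order of the Release 6 plus ISO1 MT assembly, 12 had a probe set, and 0 of the 12 passed the adjusted threshold, with 3 at an unadjusted p under 0.05. Elsewhere 1226 of 11970 genes passed, and the shares did not differ detectably (Fisher's exact test, 2-sided p = 0.625). The measured neighbours differed by -0.42 to 0.27 on the log2 scale, 10 of them lower in the null group. Several read near the floor in the wild type, among them Gr64a (2.47), CG14983 (3.09), CG10853 (3.14) and Gr64f (3.43), so a fall could hardly show there. The genes scrt and CG43915, close to FoxL1 on one side, had no probe set of their own. These values therefore do not show that the region around FoxL1 is intact. The nearest measured genes, CG14985 on one side and Mul1, a mitochondrial E3 ubiquitin ligase, on the other, differed by -0.25 (SE 0.12, limma adjusted p = 0.306) and -0.34 (SE 0.11, adjusted p = 0.121). The lowest value was that of CG11593, the outermost gene on one side, at -0.42 (SE 0.11, adjusted p = 0.0701); it passed with the replicate block (adjusted p = 0.0393) and after another quantile normalization (0.0431).

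**Figure D1:**
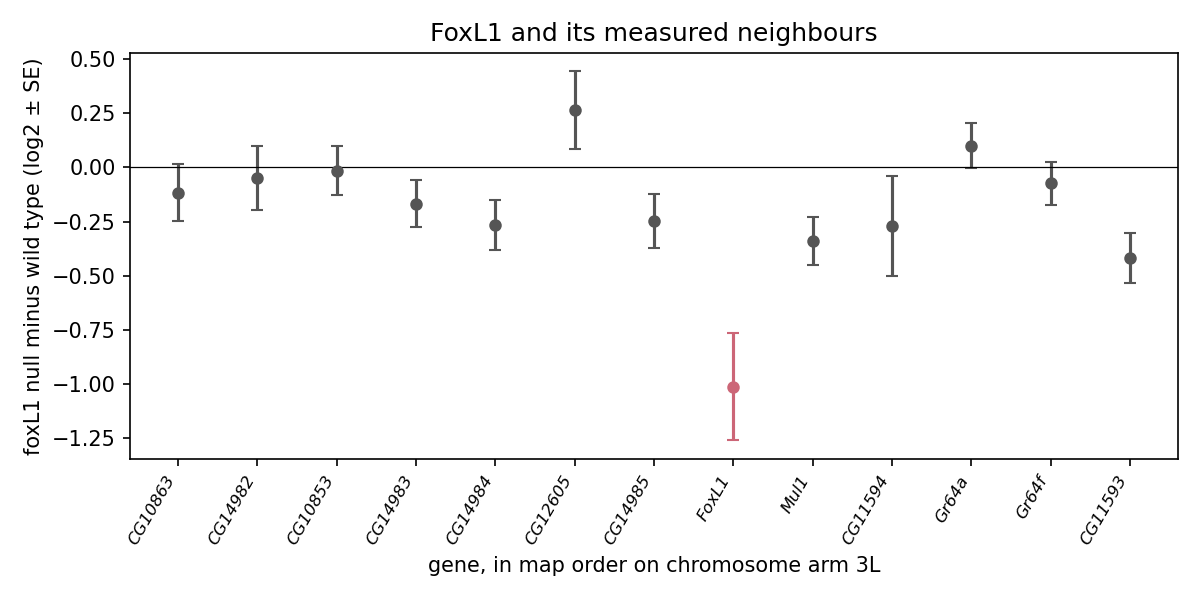
Log2 difference, null minus wild type, of FoxL1 and its 12 measured neighbours in map order on chromosome arm 3L, with the limma standard error as bars (n = 3 arrays per group; distances are not to scale). FoxL1 lies at -1.01 and its neighbours between -0.42 and 0.27.

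Across the array the null embryos differed from the wild type at 1472 of 18769 probe sets, of which 887 rose and 585 fell, and 373 of them by at least 2-fold. By each gene's brightest probe set, the rises with the greatest measured difference included that of Obp46a, an odorant-binding protein, 15.9-fold from a log2 signal of 3.79 ± 0.16 to 7.78 ± 0.27 (SD, n = 3 each; limma log2 difference 3.99, SE 0.16, adjusted p = 0.000103). CG11893 rose by 3.80 (SE 0.25, adjusted p = 0.000717), polyph, an amino acid transporter, by 3.63 (SE 0.18, adjusted p = 0.000131) and CG44005 by 3.21 (SE 0.28, adjusted p = 0.00119). The wild-type signals of CG11893 (3.13) and polyph (2.51), and that of prom (2.97), lay near the floor, which compresses a difference, so the order of these rises is not settled. Among genes with a name there followed prom, which encodes the membrane protein Prominin, at 2.75 (SE 0.16), the RNA-binding protein gene Rbm13 at 2.65 (SE 0.11) and the receptor tyrosine kinase gene tor (torso) at 2.48 (SE 0.12), with adjusted p of 0.000306, 0.000103 and 0.000116. Another prom probe set also rose, by 0.88 (adjusted p = 0.0195). The remaining prom probe set differed by -0.04 and lay near the floor of the arrays, at a log2 signal of 2.56 in the wild type and 2.51 in the null group.

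The steepest fall was that of PGRP-LE, an intracellular sensor of bacterial peptidoglycan, which went from 7.48 ± 0.15 to 4.84 ± 0.35, 6.26-fold lower (SD, n = 3 each; limma log2 difference -2.65, SE 0.18, adjusted p = 0.000734). The serine protease gene Jon44E fell by 2.45 (SE 0.47, adjusted p = 0.0199), the cytochrome P450 gene Cyp309a2 by 2.27 (SE 0.10, adjusted p = 0.000105) and CG3191 by 2.26 (SE 0.17, adjusted p = 0.000747). They were joined by 3 genes known for their activity in the cellularising blastoderm, the mitotic inhibitor gene Z600 (-2.05, SE 0.36, adjusted p = 0.0140), the lipid droplet transport gene halo (-2.05, SE 0.21, adjusted p = 0.00202) and SNCF (-2.05, SE 0.37, adjusted p = 0.0164). Without wild-type array 1 or 2, SNCF had an adjusted p of 0.0638 or 0.0507, without wild-type array 3 Z600 had 0.0509, and without null array 1 Jon44E had 0.0741.

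At 27.0% of the probe sets the 3 null values lay all above or all below the 3 wild-type values, against 10% by chance. With the replicate numbers as a block, limma called 2441 probe sets (1144 higher, 1297 lower), among them 1466 of the 1472. Leaving out wild-type array 1, 2 or 3 left 705, 799 and 663 calls, and leaving out null array 1 left 898. With each array centred on its own median the calls were 1503 (1179 higher, 324 lower), since centring moved the median difference of all probe sets from -0.03 to 0.09. An exact test of 3 against 3 arrays cannot give a p below 0.1, so the calls rest on a model of the spread. A linear model that shares no spread across probe sets called 562, of which 495 were among the 1472.

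**Figure D2:**
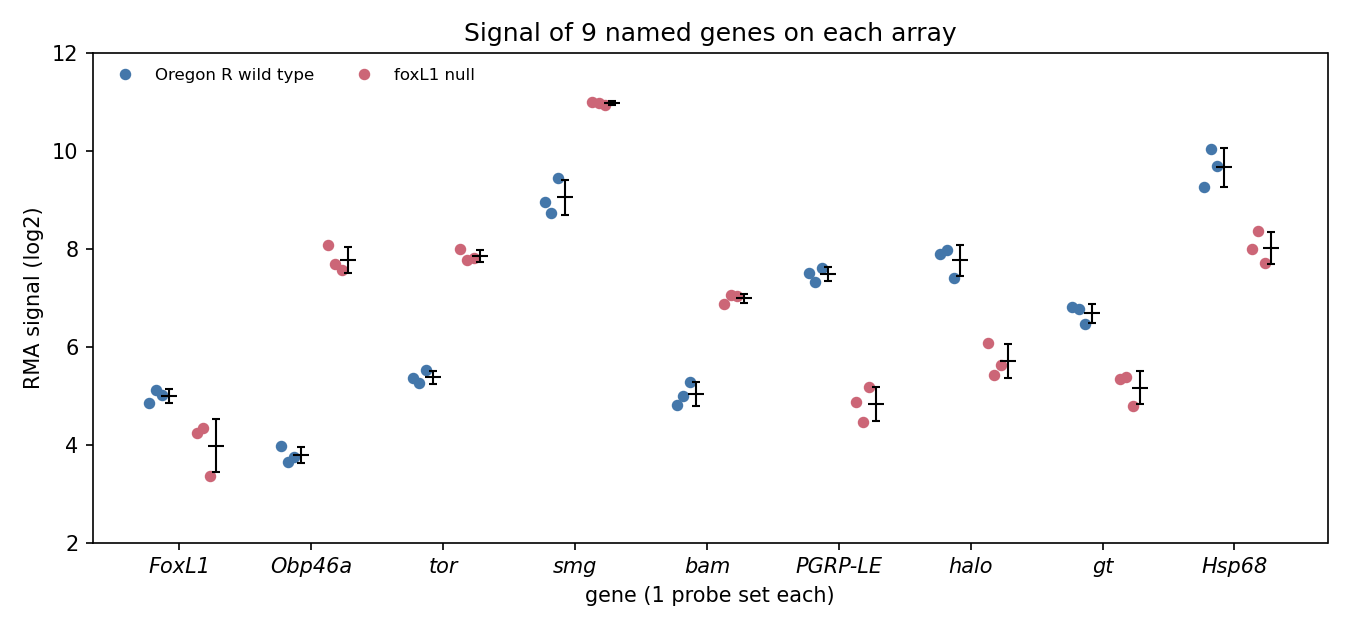
RMA signal (log2) of 9 named genes on each of the 6 arrays, 1 point per array, with the group mean and SD as a black bar beside the points (n = 3 per genotype). Obp46a, tor, smg and bam lie higher in the null embryos and FoxL1, PGRP-LE, halo, gt and Hsp68 lower, with no overlap between the genotypes.

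Transcripts that mothers load into the egg were among the strongest rises in the null embryos. Of 14 measured members of the list of yolk and maternal genes, 6 rose, 0 fell and 8 did not pass. Besides tor, they included the gene of the translational repressor Smaug, smg, which went from 9.05 ± 0.37 to 11.0 ± 0.04 (SD, n = 3 each; limma log2 difference 1.92, SE 0.18, adjusted p = 0.00145). The gene swa, whose product localises bicoid RNA, rose by 1.91 (SE 0.18, adjusted p = 0.00145) and plu, required in the first embryonic cell cycles, by 1.88 (SE 0.15, adjusted p = 0.000983). Adjusted over the list alone, 6 rose and 2 fell. The list's median was 0.05 and its mean 0.60, and over the alternatives its median ran from -0.03 to 1.16. Camera called it higher (adjusted p = 0.0373), but not with an estimated correlation (adjusted p = 0.799) and not with the replicate block (adjusted p = 0.0605). The call also ended with array weights (adjusted p = 0.160) and with each array centred on its median (0.0781). Without null array 2 its median was -0.03 (camera adjusted p = 0.169), and without null array 3 the adjusted p was 0.0873.

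Germline genes rose in part. Among 15 measured germline genes 5 rose, 0 fell and 10 did not pass, also adjusted over the list alone. The rises were those of bam, which drives germ cell differentiation, from 5.04 ± 0.24 to 6.99 ± 0.10 (SD, n = 3 each; limma log2 difference 1.95, SE 0.14, adjusted p = 0.000747), and of 4 genes of the piRNA pathway that silences transposons. These were AGO3 (1.52, SE 0.21, adjusted p = 0.00602), vret (1.15, SE 0.13, adjusted p = 0.00255), aub (0.96, SE 0.15, adjusted p = 0.00953) and piwi (0.57, SE 0.13, adjusted p = 0.0329), the last of them outside the naming rule and named after its value was seen. As a whole the germline list had a median of -0.07 and a mean of 0.23, and camera did not call it (adjusted p = 0.195). Fry's test for change in either direction did (adjusted p = 0.000194).

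Several segmentation and proneural genes fell. Of 20 measured early patterning genes 9 fell, 0 rose and 11 did not pass, and 13 fell adjusted over the list alone. The gap gene gt dropped from 6.68 ± 0.19 to 5.17 ± 0.33 (SD, n = 3 each; limma log2 difference -1.52, SE 0.18, adjusted p = 0.00339). The proneural gene ac fell by 1.37 (SE 0.19, adjusted p = 0.00571), the segment polarity gene gsb by 1.17 (SE 0.16, adjusted p = 0.00571) and the gap gene hb by 0.73 (SE 0.15, adjusted p = 0.0247). The list's median was -0.44, and -0.67 without null array 2. Camera called it lower (adjusted p = 3.83e-05), but not with an estimated correlation (adjusted p = 0.799). Of 15 neuroblast genes 3 fell, l(1)sc by 1.32 (SE 0.19, adjusted p = 0.00666), pdm2 by 0.99 (SE 0.15, adjusted p = 0.00768) and hb, and 0 rose. With the replicate block 6 fell, and adjusted over the list alone 4 fell (median -0.33, camera adjusted p = 0.00882, and 0.799 with an estimated correlation). The neuroblast call ended without null array 1 or 3 (camera adjusted p = 0.0974 and 0.0525), and that of hb without wild-type array 1, 2 or 3 or null array 1 (limma adjusted p of up to 0.103) and after centring (0.0512).

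Some genes of the visceral mesoderm and heart also fell, 5 of 13 measured, with 0 rising, and 5 fell adjusted over the list alone. They were the T-box genes Doc3 (-0.90, SE 0.17, limma adjusted p = 0.0193), Doc1 (-0.87, SE 0.17, adjusted p = 0.0236) and Doc2 (-0.69, SE 0.16, adjusted p = 0.0434), the GATA factor gene pnr (-0.83, SE 0.18, adjusted p = 0.0337) and the homeobox gene bap (-0.52, SE 0.13, adjusted p = 0.0498), the last of them named after its value was seen. The 3 Doc genes and pnr, which are also active in the amnioserosa and dorsal ectoderm, each lost their call without some single array, with adjusted p of up to 0.0773 (Doc3), 0.0925 (Doc1), 0.151 (Doc2) and 0.119 (pnr). Centring ended the calls of Doc2 (0.0803) and pnr (0.0548), and another quantile normalization that of Doc2 (0.0782). The call of bap was not followed through the alternatives. That list's median was -0.34 (camera adjusted p = 0.00249, and 0.799 with an estimated correlation). Of 19 muscle identity factors 1 fell, Six4, from 5.86 ± 0.17 to 4.88 ± 0.07 (SD, n = 3 each; limma log2 difference -0.98, SE 0.12, adjusted p = 0.00342), and 1 fell adjusted over the list alone. That list's median was -0.26 (camera adjusted p = 0.0373). Its call was lost with an estimated correlation (adjusted p = 0.799), with the replicate block (adjusted p = 0.0605) and without wild-type array 2 or 3 or null array 1 or 3 (adjusted p = 0.134, 0.0855, 0.0974 and 0.0873). It was lost too after another quantile normalization (0.0525), with probe sets above the 50th or 25th percentile of signal alone (0.0904 and 0.0637) and without genes shared by lists (0.0669).

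Of 9 measured stress and heat shock genes 3 fell and 0 rose, and 4 fell adjusted over the list alone. Hsp68 went from 9.66 ± 0.39 to 8.02 ± 0.33 (SD, n = 3 each; limma log2 difference -1.65, SE 0.23, adjusted p = 0.00609), Hsp26 fell by 1.54 (SE 0.28, adjusted p = 0.0174) and the cochaperone gene DnaJ-1 by 0.90 (SE 0.20, adjusted p = 0.0349). Hsp26 and DnaJ-1 lost the call without some single array (adjusted p of up to 0.0789 and 0.125), and DnaJ-1 after centring (0.0661). The list's median was -0.44 (camera adjusted p = 0.0373, and 0.799 with an estimated correlation). Its call ended without wild-type array 2 or 3 or null array 1 or 3 (camera adjusted p = 0.0871, 0.0587, 0.0974 and 0.102). It also ended with probe sets above the 50th or 25th percentile of signal alone (0.0992 and 0.0637). Among oxidative phosphorylation genes the differences were small. In this list 0 of 28 passed limma's threshold on their own, also adjusted over the list alone, with 12 at an unadjusted p under 0.05 and 2 passing as lower with the replicate block. Of the 28, 27 were lower, with a median of -0.24 (camera adjusted p = 0.000871, and 0.799 with an estimated correlation).

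None of the 7 list calls held with a correlation estimated per list (lowest adjusted p 0.799), and fry, which tests whether a list's genes move one way on balance, called 0 of the 32 lists (lowest adjusted p 0.0574). Testing for change in either direction, fry called 16. Among them were the germline and detoxification lists (adjusted p = 0.000194 each), cell cycle (0.000265) and ecdysone (0.00197), which camera did not call. Centring each array on its median moved list medians upward, to -0.12 for oxidative phosphorylation, -0.15 for muscle identity, -0.21 for neuroblast, -0.23 for visceral mesoderm and heart genes and 0.17 for yolk and maternal genes. The median difference over all genes was -0.07, and 31 of the 32 list medians lay below 0.

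**Figure D3:**
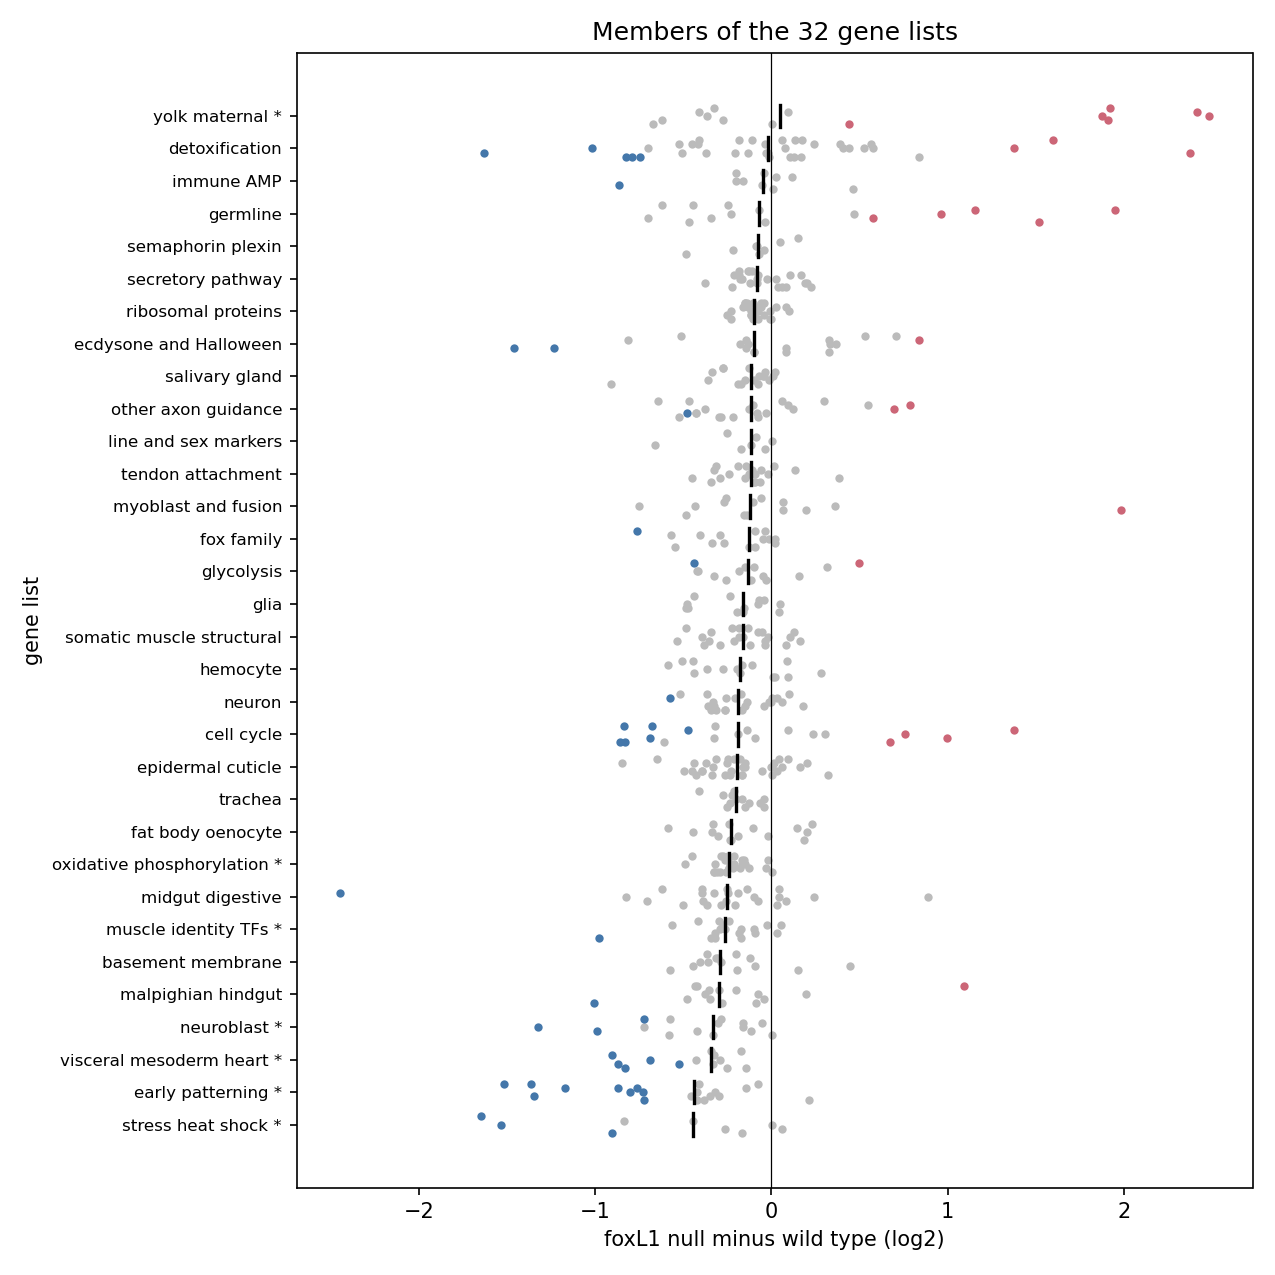
Log2 difference, null minus wild type, of each measured member of the 32 gene lists, 1 point per gene and 1 row per list, ordered by median (black bar). Red and blue points passed the limma threshold as higher and lower, grey points did not, and an asterisk marks the 7 lists that camera called with its preset correlation; early patterning and stress genes reach the lowest medians, -0.44 each.

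Among guidance genes, no semaphorin or plexin gene passed, 0 of 8, with 1 at an unadjusted p under 0.05: Sema5c, at -0.49 (SE 0.15, limma adjusted p = 0.0927), which passed with the replicate block (adjusted p = 0.0491). PlexB differed by -0.09 (SE 0.18) and Sema2b by 0.15 (SE 0.10). Among 22 other axon guidance genes 2 rose and 1 fell, and 3 rose and 4 fell adjusted over the list alone and also with the replicate block. Camera did not call this list (adjusted p = 0.786), while fry's test for change in either direction did (adjusted p = 0.00197). Ephrin rose from 7.80 ± 0.02 to 8.58 ± 0.20 (SD, n = 3 each; limma log2 difference 0.78, SE 0.12, adjusted p = 0.00908). The receptor tyrosine phosphatase gene Ptp10D rose by 0.70 (SE 0.13, adjusted p = 0.0178) and the cell adhesion gene Dscam1 fell by 0.48 (SE 0.12, adjusted p = 0.0464), and both lost the call without some single array (adjusted p of up to 0.0773 and 0.149), Dscam1 also after centring (0.170). A second Ptp10D probe set, at a log2 signal of 5.15, differed by 0.01 (SE 0.12, adjusted p = 0.981). For Dscam1 a second probe set, near the floor at 3.15 in the wild type, differed by 0.09 (SE 0.14, adjusted p = 0.781). The midline sorting gene comm was at -0.65 (SE 0.17, adjusted p = 0.0593). It passed with the replicate block (adjusted p = 0.0123), with array weights (0.0194), after another quantile normalization and without null array 2 (0.0228). Of 18 salivary gland genes 0 passed. Only 1 had an unadjusted p under 0.05, hkb, a factor that positions gland invagination, at -0.91 (SE 0.23, limma adjusted p = 0.0530), while the gland selector fkh was at -0.34 (SE 0.19). The fall of hkb passed with the replicate block (adjusted p = 0.00638), with array weights (0.0170), after another quantile normalization (0.0398), with trend and robust estimation (0.0444) and without null array 2 (0.0175). Without null array 2 fkh passed too, at -0.55 (adjusted p = 0.0494).

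Structural genes of the body wall muscle and of its attachments did not pass the threshold without the block either. The 23 measured sarcomere and muscle genes had 0 calls and 2 with an unadjusted p under 0.05, l(2)efl at -0.48 (SE 0.19) and Zasp52 at -0.39 (SE 0.15), with a median of -0.16 (camera adjusted p = 0.316). With the replicate block 2 of the 23 fell, l(2)efl among them (adjusted p = 0.0412). Without wild-type array 2 camera called this list lower (median -0.29, adjusted p = 0.0291). The 20 tendon and attachment genes had 0 calls and 4 with an unadjusted p under 0.05, among them Ilk at 0.38 (SE 0.14) and the integrin gene mew at -0.45 (SE 0.18), with a median of -0.12 (camera adjusted p = 0.313). Adjusted over each list alone, no semaphorin, salivary gland, muscle or attachment gene passed, and fry called none of these 4 lists by either of its tests. Of 14 measured members of the myoblast and fusion list 1 rose, Nach, from a wild-type signal at the floor, 2.70 ± 0.19, to 4.69 ± 0.65 (SD, n = 3 each, limma log2 difference 1.99, SE 0.30, adjusted p = 0.00757). The place of Nach in this list was not checked here, so its rise is not read as a change of myoblasts or their fusion. The mesoderm determinant twi was at -0.75 (SE 0.19, adjusted p = 0.0528), and adjusted over the list alone 1 rose and 1 fell. It passed with the replicate block (adjusted p = 0.00442), after another quantile normalization (0.0446) and with trend and robust estimation.

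Cell cycle genes moved in both directions. Of 19 measured, 4 rose and 6 fell (5 and 7 adjusted over the list alone). Camera called no shift of the list one way (median -0.19, adjusted p = 0.786), while fry's test for change in either direction called it (adjusted p = 0.000265). The replication origin gene Orc1 rose by 1.38 (SE 0.13, limma adjusted p = 0.00159). The cyclin gene CycB rose from 10.8 to 11.8 (SE 0.14, adjusted p = 0.00618) and CycB3 by 0.76 (SE 0.12, adjusted p = 0.00812). The DNA polymerase gene PolA1 fell by 0.83 (SE 0.13, adjusted p = 0.00867). Detoxification genes did likewise, with 3 of 38 rising and 5 falling (4 and 7 adjusted over the list alone, 5 and 8 with the replicate block, camera adjusted p = 0.840). The P450 gene Cyp12d1-d rose by 2.37 from a wild-type signal near the floor, 3.06, so the difference is a lower limit (SE 0.19, adjusted p = 0.00102), and the metallothionein gene MtnA by 1.37 (SE 0.15, adjusted p = 0.00272), while Cyp6a13 fell by 1.63 (SE 0.17, adjusted p = 0.00232) and Cyp28a5 by 1.02 (SE 0.12, adjusted p = 0.00339). Of 19 ecdysone genes 2 fell, the steroid hydroxylase genes dib (-1.46, SE 0.17, adjusted p = 0.00337) and spo (-1.24, SE 0.20, adjusted p = 0.0110), and 1 rose, nvd (0.84, SE 0.18, adjusted p = 0.0305). With the replicate block 3 fell and 2 rose. The signal of nvd lay near the floor, at 2.69 and 3.53, and its call ended without some single array (adjusted p of up to 0.110).

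At most 2 members passed in each of 6 further lists that camera did not call. Of 24 neuron genes 1 fell, the SNARE gene Snap25, at -0.58 (SE 0.10, limma adjusted p = 0.0111). Of 15 other forkhead genes 1 fell, slp2, at -0.76 (SE 0.19, adjusted p = 0.0482). Of 10 measured genes in the list of antimicrobial peptides and peptidoglycan recognition 1 fell, BomS2, at -0.87 (SE 0.21, adjusted p = 0.0487). Of 14 glycolysis and glycogen genes, the glycogen synthase gene Glys rose by 0.50 (SE 0.10, adjusted p = 0.0205) and Pgi fell by 0.44 (SE 0.10, adjusted p = 0.0446). Of 15 Malpighian tubule and hindgut genes, the potassium channel gene Irk3 fell by 1.01 (SE 0.16, adjusted p = 0.00909) and the zinc transporter gene ZnT35C rose by 1.09 (SE 0.24, adjusted p = 0.0312). Of 25 midgut genes Jon44E alone passed. With the replicate block 3 forkhead genes fell, as did 2 each of the neuron, midgut, glycolysis and Malpighian tubule lists, and 1 antimicrobial peptide gene rose. Without wild-type array 2 camera called the neuron (adjusted p = 0.0113), midgut (median -0.69, 0.00708) and Malpighian tubule (0.0394) lists lower, and without null array 2 the forkhead list (median -0.29, 0.0144). All of these except Irk3 lost the call without some single array (adjusted p of up to 0.0563 for Snap25, 0.141 for slp2, 0.165 for BomS2, 0.0898 for Glys, 0.181 for Pgi and 0.111 for ZnT35C; Jon44E is given above). Centring ended the calls of slp2 (0.0922), BomS2 (0.0715) and Pgi (0.145), and another quantile normalization those of BomS2 (0.0879) and Pgi (0.0583).

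Other tissues and housekeeping groups had no gene past the threshold without the block. In limma 0 members were called among 14 basement membrane, 15 hemocyte, 13 glia, 13 trachea, 36 cuticle, 15 fat body and oenocyte, 30 ribosomal protein and 24 secretory pathway genes and among 7 markers of line and sex. With oxidative phosphorylation, semaphorins, salivary gland, muscle and attachment, these 14 lists held 264 measured members, of which 39 had an unadjusted p under 0.05, and their medians ran from -0.29 to -0.08. With the replicate block limma called 13 of the 264, all lower, among them 3 cuticle, 2 basement membrane and 1 hemocyte gene. Camera called none of these lists apart from oxidative phosphorylation, though without wild-type array 2 it called cuticle, basement membrane (adjusted p = 0.0394 each) and muscle lower. Fry's test for change in either direction called basement membrane (adjusted p = 0.00784), oxidative phosphorylation (0.0286) and fat body (0.0420).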

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

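The test on the other control probe sets was chosen after the result was seen.

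Outside the tested genes, 1 of the 183 control probe sets stood far higher in the null embryos, a signal that the comparisons of genes do not use. Its log2 signal was 3.97 ± 0.08 in the wild type and 8.94 ± 0.27 in the null group (SD, n = 3 each), a difference of 4.97 (SE 0.14, limma adjusted p = 1.72e-08), higher in 3 of 3 null arrays. A shift of all control signals between the groups is argued against by the other 182 control probe sets, none of which differed by more than 0.399 in either direction (lowest limma adjusted p 0.855, 7 at an unadjusted p under 0.05). What this probe set detects is not given in the sources used here, and a candidate explanation that stays open is a sequence, such as a marker or vector, that the null line carries and Oregon R lacks. The design ties the genotype to the line, so no test here separates it from an effect of losing foxL1.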

How the results depend on the processing

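Of the alternatives, all fixed before the data were examined, none turned the direction of FoxL1, of a named gene past the threshold or of a called list by its test. Against 1472 called probe sets, the replicate block gave 2441, array weights 2460, the unmoderated model 562 and a minimum fold of 2 gave 373; leaving out single arrays gave 663 to 1513, and the remaining alternatives lay within 1.5 times. The share of higher calls, 60.3%, was 78.4% after centring each array on its median and 46.9% with the replicate block. The FoxL1 difference ran from -1.20 to -0.71 when single arrays were left out, with adjusted p from 0.0210 to 0.155, and was -0.93 (adjusted p = 0.0761) after another quantile normalization and -0.90 (adjusted p = 0.0641) after centring; averaging its probe sets was not run, since 1 probe set names the gene. Among the neighbours 1 gene, CG11593, was called with the replicate block and 1 after another quantile normalization, and 0 when any single array was left out. Against 7 called lists, camera with an estimated correlation gave 0, directional fry 0 and mixed fry 16, and leaving out single arrays gave 3 to 11. The replicate block gave 5 lists and ended the calls of the muscle identity and maternal lists; it changed no other list call. Where fewer arrays entered the fit, the spread rested on fewer samples; in the other cases the cause was not tested. Of the 57 named genes past the threshold besides FoxL1, 38 passed whichever single array was left out. The alternative for linear values was not run, since the values are on a log2 scale, and signal near the floor limits what can be said of weakly expressed genes such as FoxL1.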

Other observations

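The gene groups, the singled-out genes and all tests in this part were chosen after the results were seen, except that the splits of the arrays for lists and neighbours and the test on egg genes not looked at before were fixed before those values were seen.

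Beyond the germline list, several genes of the piRNA pathway and its perinuclear granules rose in the null embryos and a few fell. In a group written after the largest changes were known, 11 of 24 measured members rose and 3 fell, and among the 20 not looked at before, 7 rose and 3 fell, with a mean difference of 0.16 (95% interval -0.07 to 0.39). The rises included mael (1.97, SE 0.17, limma adjusted p = 0.00125), squ (1.73, SE 0.10, adjusted p = 0.000312), tej (1.66, SE 0.16, adjusted p = 0.00165) and SoYb (1.19, SE 0.16, adjusted p = 0.00477), and the falls cuff (-1.13, SE 0.14, adjusted p = 0.00339), Hen1 (-0.97, SE 0.11, adjusted p = 0.00267) and vls (-0.68, SE 0.16, adjusted p = 0.0453). Of 24 genes of oocyte meiosis 4 rose and 1 fell, the synaptonemal complex genes corolla (1.92, SE 0.19, adjusted p = 0.00163) and c(3)G (1.73, SE 0.13, adjusted p = 0.000779) among the rises, but among the 21 not looked at before 1 rose and 1 fell. Of 33 other genes listed as active in the egg 13 rose and 1 fell. The rises included twe, a meiotic Cdc25 phosphatase (2.23, SE 0.24, adjusted p = 0.00253), wisp, a cytoplasmic poly(A) polymerase (1.77, SE 0.17, adjusted p = 0.00159), and the dorsal pathway gene ea (1.16, SE 0.11, adjusted p = 0.00159). Among the 28 not looked at before 11 rose and 1 fell, vir-1. That gene is better known for its response to viruses and was probably listed in place of a gene with a like symbol.

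Some targets of Notch signalling and some blastoderm genes fell. Of 13 Enhancer of split and Bearded family genes 6 fell and 0 rose, with E(spl)m4-BFM at -1.64 (SE 0.23, limma adjusted p = 0.00571), E(spl)mdelta-HLH at -1.33 (SE 0.20, adjusted p = 0.00812) and Brd at -1.08 (SE 0.13, adjusted p = 0.00360). Among the 10 of them not looked at when the group was written, 3 fell and 0 rose (median -0.67). Of 16 cellularisation genes 5 fell and 2 rose, with bnk going from 4.84 to 3.84 (SE 0.12, adjusted p = 0.00309) beside halo, Z600 and SNCF, and dah at 1.61 (SE 0.12, adjusted p = 0.000779), but among the 10 not looked at before 1 rose and 1 fell. Of 16 zygotic genes of the dorsoventral axis 4 fell and 0 rose, among them zen (-0.98, SE 0.15, adjusted p = 0.00932) and tld (-0.76, SE 0.14, adjusted p = 0.0188), and among the 9 not looked at before 2 fell and 0 rose.

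Some maternal transcripts were higher and some early zygotic genes lower in the null arrays. The mean of the early patterning list was lower (difference -0.62, 95% interval -1.01 to -0.22), where younger null embryos would raise it. The mean of the yolk and maternal list was higher by 0.60 (interval 0.27 to 0.94), where older ones would lower it. Its median was 0.05 (-0.03 to 1.16 over the alternatives), and 6 of its 14 members were lower. These lists are the pattern itself, so they are no separate test of age. They show only that youth alone would not give the zygotic part, nor greater age the maternal rises. For the zygotic part the cuticle, digestive and muscle lists, at -0.22 (interval -1.01 to 0.58), leave greater age open. Without wild-type array 2, camera called each of these lists lower (adjusted p = 0.0394, 0.00708 and 0.0291). Undeveloped eggs that kept every egg transcript would raise egg transcripts by amounts that depend on each gene's own level in embryos. The members that did not rise included osk (-0.62, SE 0.26), gnu (-0.67, SE 0.31), png (-0.41, SE 0.12) and exu (-0.33, SE 0.14). In all, 9 of the 14 members had an upper 95% bound below 1. Without the yolk protein genes that count was 6 of 11, and 6 of the 11 had a lower bound above 0. The bound of 1 assumes a like rise for every member and was set after the values were seen. These counts therefore show only that the list did not rise as a whole, and they do not decide on such eggs. Eggs that kept part of their transcripts cannot be told apart from the alternatives. Of 40 meiosis and piRNA genes not looked at before 8 rose and 4 fell (exact binomial test, 1-sided p = 0.194). The test takes the genes as independent, each with an even chance of rising, although 61.0% of all called genes rose. Of 28 other egg genes not looked at before 11 rose and 1 fell. A difference between the lines in what mothers deposit or embryos clear, and the loss of foxL1 in mother or embryo, may each account for the maternal part and were not tested.

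The probe sets of RFeSP, a subunit of respiratory complex III, disagreed between the genotypes. One of them rose from a log2 signal of 3.18 ± 0.19 to 8.08 ± 0.09 (SD, n = 3 each; limma difference 4.90, SE 0.13, adjusted p = 8.06e-06), while the brighter one, at 10.6 and 10.3, differed by -0.33 (SE 0.11, adjusted p = 0.148). A change in the level of all RFeSP transcripts is argued against by the brighter probe set, whose 95% interval of -0.64 to -0.01 excludes a rise. A transcript form or a sequence difference between the lines under the probes of the dimmer set may account for it, and neither was tested. Of the 37 probe sets that name 1 gene and changed by at least 2 on the log2 scale, 3 had another probe set of the same gene at a signal of 6 or more, and the other 2, both of bcd, rose together.

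The called probe sets were spread over the chromosome arms, with 9.23% of genes called on arm 4 to 11.3% on arm X and 10.3% on arm 3L, which holds FoxL1 (chi-square test over 6 arms, p = 0.577). The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1472 probe sets and the highest of the others 5, so no other split gave as many as the real one. For the gene lists, the real split gave 7, and 5 of the 10 splits, the real one included, gave 7 or more. The highest, 18, set wild-type array 1 with null arrays 1 and 3, which points to a structure among the arrays besides genotype. For the neighbours the count was 0 in the real split and at most 0 in the others, so all 10 were alike. Among the 4 splits that part all 3 same-numbered pairs, the other 3 gave 0 probe sets each and 3, 6 and 9 lists.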
